A study of Mus musculus with 4 samples.

How the data were processed

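Gene expression was measured by RNA-seq in mouse pancreatic organoids at day 7, in 2 samples with mutant KRAS and 2 with KRAS and overexpressed SPIB. Per the labels' protocols, RNA was taken with an RNeasy plus mini kit and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. The submitters' processing notes name bcl2fastq 2.19, kallisto 0.44.0, sleuth and DESeq2 as tools and GRCh38, GRCm38 and mm10 as builds, with no role for each. The annotation release, the strand setting of the counting and the steps that the authors ran on these samples beyond those names are not given in the sources used here.

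The authors deposited 1 table with an estimated count per gene and library, per the file headers, and 1 table of TPM (transcript abundance scaled for transcript length and to a fixed total). The estimated counts were not whole, and they were rounded to whole numbers before any count test. The deposited TPM values served as an alternative unit and for effective length. The columns name 2 controls and 2 SPIB samples, and the controls were taken as the KRAS samples with the same numbers, since KRAS is the group in the labels without SPIB. Each table lists 35199 genes by symbol, and 0 columns belonged to no sample. Of these symbols 34505 were found once in GENCODE M21 for GRCm38, from which positions, strands, overlapping genes, GC content, transcript length and annotated retained introns were taken. Whether the authors used that release is not known, so positions are those of GENCODE M21.

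Library totals were 37327762 and 35129432 counts for KRAS replicates 1 and 2 and 36826918 and 36028302 for SPIB replicates 1 and 2. A gene with 0 counts in a library could have had up to 3 counts, which is 0.0804 to 0.0854 CPM (counts scaled to library size). Per tested gene, the counts of a replicate pair had a median chi-square of 3.33 in KRAS and 5.14 in SPIB organoids, where counting error alone gives 0.455. The 2 libraries per group leave 2 residual degrees of freedom.

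Genes were kept with edgeR's filterByExpr at its default settings (a count of 10 in a library of median size, 15 in all), which left 14563 genes and set aside 20636. Libraries were scaled by TMM. The groups were compared with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test with group as the only term, fitted to all 4 libraries, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are SPIB minus KRAS organoids. The standard error (SE) of an edgeR fit was back-calculated as the absolute log2 fold change over the square root of the F statistic. CPM values are TMM-normalised means with the SD of 2 libraries. Plots were drawn with matplotlib 3.10.9.

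For 24 gene lists with 568 members in all, camera of limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 24 lists, and camera with an estimated correlation and fry were run beside it. The lists were tuft cell, M cell, Ets factor targets of B and dendritic cells, acinar cell, ductal cell, gastric and mucous metaplasia, endocrine cell, RAS-ERK output, type 2 alarmins and eicosanoid enzymes, interferon response, antigen presentation, NF-kB and chemokine, cell cycle, mesenchymal transition, p53 response, unfolded protein and amino acid stress, Wnt and Notch targets, sterol and fatty acid synthesis, hypoxia and glycolysis, fibroblast and stellate cell, endothelial cell, macrophage and T cell, mitochondrially encoded and ribosomal protein. The design, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule named Spib, Kras, Dclk1, Pou2f3 and Il25, the 12 genes per direction with the largest log2 fold change among calls with a mean of at least 5 CPM in the higher group and groups that did not overlap (predicted, clone-named and numbered pseudogene symbols left out), and up to 4 tested members per list with the smallest p. Further list members named in the text without being among those 4 were chosen after their values were seen.

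The count and list tests were tested on simulated data for this comparison, with 200 of 14300 tested genes changed. The edgeR test recovered 34.3% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 89.4% of those changed 4-fold, and 11.6% of its calls were unchanged genes. With no gene changed it made 2 calls, and camera called 0 lists. Each gene was simulated independently of the others, so these 0 lists do not test camera where list members vary together. In the real libraries the estimated correlation reached 0.97, for the mitochondrially encoded list.

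Alternatives set in advance were DESeq2 size factors, upper-quartile scaling, library size alone, no filter on low counts, at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, a fold change of at least 2, limma on log2(TPM + 1) and on log2(TPM + 0.1) with at least 1 TPM in 2 libraries and without a filter, the replicate number as a block, and each library left out in turn, where a lone library is assumed to vary like the pair of the other group. For lists, the list without its member with the smallest p was added to these. Alternatives chosen after the data were seen were leaving out the 13 mitochondrially encoded genes, the mitochondrial share as a covariate, and removal of smooth trends with GC content and length, for which 13684 tested genes (94.0%) had values. The single-cell part of the study was not analysed here.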

Results

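The data were 4 RNA-seq libraries of mouse pancreatic organoids, epithelial structures that grow in culture from dissociated pancreas cells, collected at day 7. In 2 libraries the organoids carried mutant KRAS, a small GTPase mutated in most pancreatic cancers, and they are called KRAS organoids here. In the other 2 libraries the organoids carried KRAS and also overexpressed SPIB, an Ets-family transcription factor known from B cells, plasmacytoid dendritic cells and intestinal M cells, and they are called SPIB organoids here. Estimated counts per gene summed to 37327762 in KRAS replicate 1, 35129432 in KRAS replicate 2, 36826918 in SPIB replicate 1 and 36028302 in SPIB replicate 2, so depth differed little between the groups. Of 35199 genes listed, 19023 and 18848 had a count in the KRAS libraries and 18062 and 17891 in the SPIB libraries. The labels number the replicates and do not say whether they came from separate cultures or animals, so the p-values below measure only the spread between these samples, which may be technical. The replicates of a group differed from each other by more than counting error, with a chi-square of 44.5 per degree of freedom for the KRAS pair and 55.7 for the SPIB pair, so no library was counted as a repeat of another.

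The comparison of SPIB with KRAS organoids addressed which gene programs respond to SPIB in early pancreatic neoplasia, within a study of cells that express Dclk1, a kinase used as a marker of tuft cells. Spib itself rose 69.4-fold in SPIB organoids (log2 fold change 6.12 ± 0.23, SE, n = 2 per group). Dclk1 rose 1.70-fold (log2 0.76 ± 0.13), while of 25 tuft cell markers tested, Dclk1 among them, 2 rose, 4 fell and 19 were not called, and the list did not pass its set test (adjusted p = 0.0943). Of 24 ductal epithelial markers 10 rose, as did 15 of 33 cell cycle genes, 8 of 17 genes of antigen presentation and 7 of 24 genes of sterol and fatty acid synthesis. Of 13 mitochondrially encoded genes 10 fell, as did 12 of 29 ribosomal protein genes, and Rgs11 fell 10.6-fold. Of all 14563 genes tested, 2132 were higher and 2570 lower. The ductal, cell cycle, antigen presentation, sterol, mitochondrial and ribosomal lists passed the set test with a preset correlation. None passed with an estimated correlation (adjusted p = 0.769), a version of camera in which none of the 24 lists passed. It rests on 2 residual degrees of freedom and had little power. Its result therefore does not decide whether members that vary together account for the passes. With the mitochondrial share of the libraries as a covariate these lists held 0 called members, except 1 lower ribosomal protein gene. That fit left 1 residual degree of freedom and called 10 genes higher and 37 lower in all. The share accounts for 75.4% of the variance of the group label, so the fit hardly separates share from group. The medians went from 0.43 to 0.30 (ductal), 0.34 to 0.43 (cell cycle) and 0.26 to 0.30 (antigen presentation). They went from 0.28 to 0.15 (sterol), -0.38 to -0.47 (ribosomal) and -1.15 to -0.06 (mitochondrial).

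With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2132 genes were higher and 2570 lower in SPIB organoids among 14563 tested. The higher genes had a median log2 fold change of 0.49 and the lower genes of -0.84, and a change of at least 2-fold was reached by 55 higher and 1055 lower genes. The share of calls in the higher direction was 45.3%, and it was 32.3% with upper-quartile scaling, 68.1% on log2(TPM + 1) values and 68.8% after trends with GC content and length were removed, an analysis added after the data were seen. Without KRAS replicate 1 the test called 111 genes higher and 561 lower, and without KRAS replicate 2 it called 418 higher and 1219 lower. Among the higher genes, 105 of those 111 and 401 of those 418 were among the higher calls from all 4 libraries.

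Spib, which stands first because it checks the labels, had 24 and 14 estimated counts in the KRAS libraries and 1480 and 1140 in the SPIB libraries. The mean was 0.516 ± 0.174 CPM (counts scaled to library size and TMM-normalised; SD, n = 2) in KRAS and 36.2 ± 5.30 in SPIB organoids, and the adjusted p was 3.16e-12. The gene (ENSMUSG00000008193.13) lies on chromosome 7 from 44525993 to 44532071 on the minus strand of GRCm38. The counts do not tell the introduced sequence from the endogenous gene. Kras stood at 80.9 ± 12.2 CPM in KRAS and 64.4 ± 1.32 CPM in SPIB organoids, a log2 fold change of -0.33 ± 0.13 that did not pass the test (adjusted p = 0.0582). Dclk1, on chromosome 3 from 55242364 to 55539068, was at 27.2 ± 0.0351 CPM in KRAS and 46.2 ± 2.37 CPM in SPIB organoids (adjusted p = 0.000279), and its call held without any 1 of the 4 libraries. With the mitochondrial share as a covariate, added after the data were seen, Dclk1 was not called (log2 0.71 ± 0.34, adjusted p = 0.996), nor was it on log2(TPM + 1) values without a filter (adjusted p = 0.111). Pou2f3, the transcription factor that specifies tuft cells, was near the floor, with 12 and 18 counts in the KRAS libraries and 2 and 16 in the SPIB libraries, and it did not pass the test (log2 -0.70 ± 0.74, adjusted p = 0.493). Without SPIB replicate 2 it was called lower (log2 -2.84, adjusted p = 0.0396), and without SPIB replicate 1 its log2 fold change was 0.15. Il25, the tuft cell cytokine that activates type 2 innate lymphoid cells, had 0 counts in all 4 libraries, where 3 counts would be 0.0804 to 0.0854 CPM. That floor covers counting error only.

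**Figure D1:**
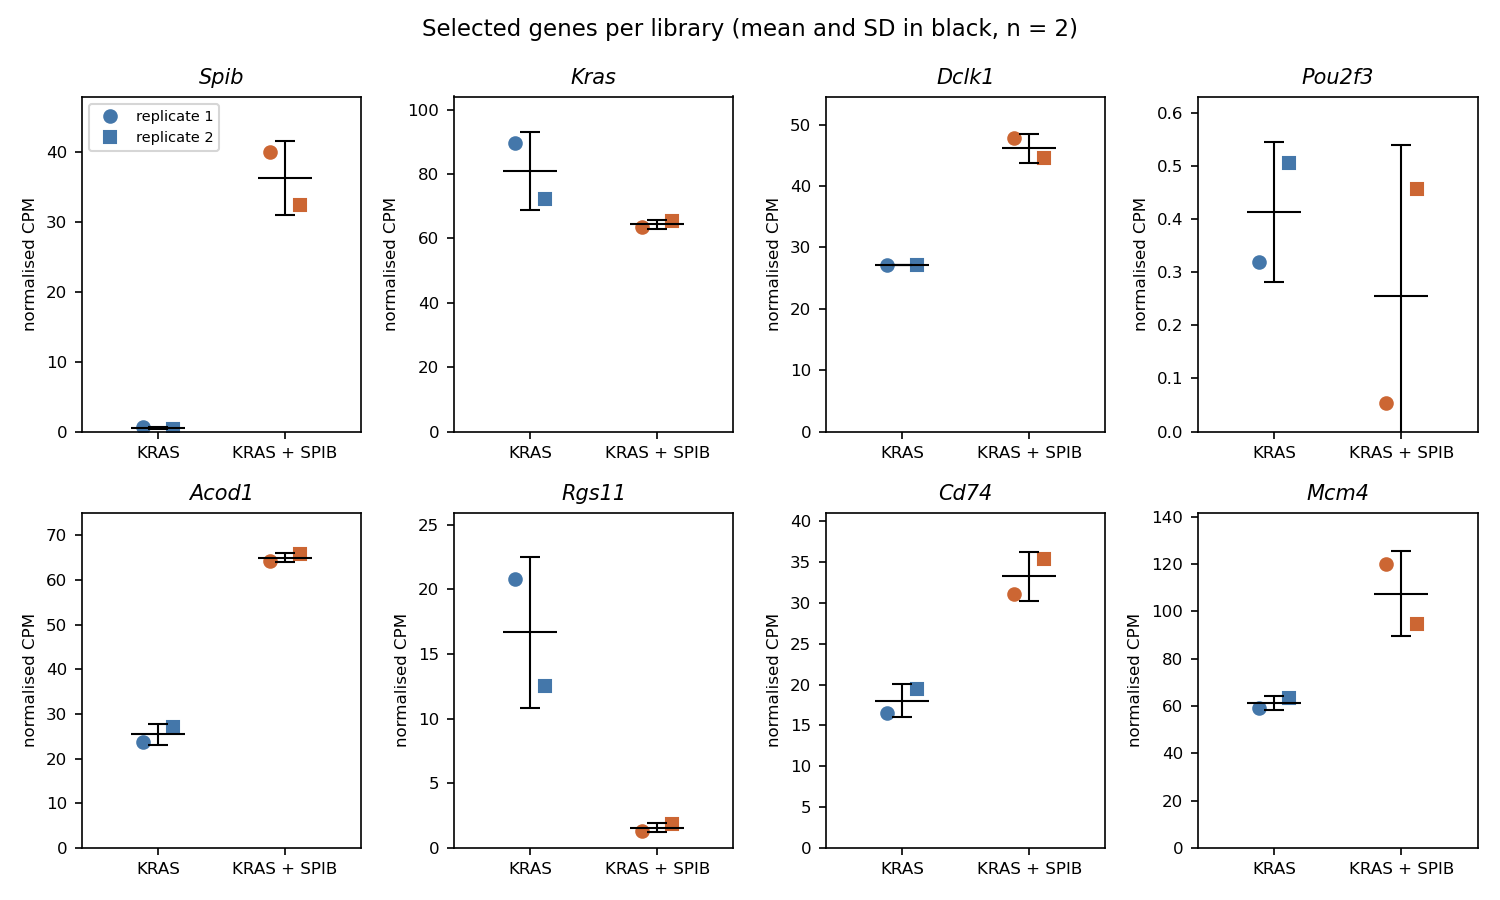
Normalised CPM (vertical axis, linear and starting at 0) of 8 named genes in the KRAS and SPIB libraries, with circles for replicate 1, squares for replicate 2 and black bars for the mean and SD (n = 2 per group). Spib, Dclk1, Acod1, Cd74 and Mcm4 lay higher in both SPIB libraries than in either KRAS library and Rgs11 lay lower, while the Pou2f3 values of the groups overlapped.

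After Spib, the genes with the largest rise included Acod1, the enzyme that makes itaconate in activated macrophages, which went from 25.5 ± 2.37 to 65.1 ± 1.05 CPM (SD, n = 2; log2 1.35 ± 0.13, adjusted p = 2.26e-06). The collagen IV chains Col4a1 (log2 1.07 ± 0.19) and Col4a2 (log2 1.08 ± 0.18), the basement membrane protein Nid1 (log2 1.18 ± 0.19), the adhesion molecule Emb (log2 1.32 ± 0.14) and N-cadherin, Cdh2 (log2 1.07 ± 0.23), all rose. Col4a1 went from 231 ± 38.7 to 487 ± 131 CPM and Nid1 from 26.2 ± 6.22 to 59.2 ± 11.9 CPM. Col4a1 and Col4a2 lie head to head on chromosome 8 at 11198423 to 11312826 and 11312805 to 11449287, where their annotations overlap. The other genes named among the largest rises were Fgf13 (log2 1.16), the pyrophosphate transporter Ank (log2 1.13), the magnesium transporter Slc41a2 (log2 1.11), the secreted Wnt antagonist Sfrp1 (log2 1.11) and carboxypeptidase E, Cpe (log2 1.07), with adjusted p between 2.62e-05 and 0.00105. Of these 12 genes, 10 kept the call without KRAS replicate 1, Cdh2 and Col4a1 being lost, and all 12 kept it without each of the other libraries.

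Rgs11, a regulator of G protein signalling on chromosome 17 from 26202951 to 26211324, had the largest fall under the naming rule, from 16.7 ± 5.84 to 1.57 ± 0.354 CPM (SD, n = 2; log2 -3.40 ± 0.28, adjusted p = 9.3e-06). Spaca6, a sperm membrane protein gene whose annotated locus also holds the microRNA genes Mir99b, Mirlet7e and Mir125a, went from 75.9 ± 23.5 to 13.6 ± 0.986 CPM (log2 -2.48 ± 0.21, adjusted p = 0.000154). Cpt1b, the muscle form of carnitine palmitoyltransferase, fell (log2 -2.57 ± 0.40), as did Tgfbr3l (log2 -2.64 ± 0.28) and Tnni2, a skeletal muscle troponin (log2 -2.26 ± 0.39). Lime1 (log2 -2.34) and the pseudogene Slc2a4rg-ps (log2 -2.42) fell, and these lie next to each other on chromosome 2, at 181380078 to 181383628 and 181384250 to 181387586. Kifc2 (log2 -2.41), Acrbp (log2 -2.38), Gdpd3 (log2 -2.25) and Srcin1 (log2 -2.22) also fell, with adjusted p between 2.31e-06 and 0.00055. Lime1, Kifc2, Acrbp and Rgs11 overlap the annotated neighbours Zgpat, Cyhr1, 4930557K07Rik and Arhgdig, and no source used here states whether strand entered the counting, so part of their counts may belong to those genes. mt-Nd6, on the minus strand of the mitochondrial genome at 13552 to 14070, overlaps only the end of mt-Nd5, at 11742 to 13565. It went from 13.4 ± 8.09 to 1.56 ± 0.294 CPM (log2 -3.11 ± 0.62, adjusted p = 0.0426). The mt-Nd6 call was lost without SPIB replicate 1 and without SPIB replicate 2. The other 11 of these 12 genes kept the call without each of the 4 libraries.

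Of 25 tuft cell markers tested, 2 rose and 4 fell, and the counts adjusted over the list alone were also 2 and 4. Besides Dclk1, Kctd12 rose (log2 0.80 ± 0.24, from 3.30 to 5.76 CPM). Fyb, an adaptor protein of haematopoietic cells on chromosome 15, fell by 4.42 ± 0.37 on the log2 scale, from 4.83 to 0.221 CPM, with an adjusted p of 1.03e-06. Il17rb, the receptor for Il25, fell from 3.92 to 1.39 CPM (adjusted p = 0.00144). Trpm5 (log2 -1.84 ± 0.61) and Rgs13 (log2 -2.01 ± 0.61) also fell, from levels of 0.656 and 0.742 CPM. The list did not pass the camera set test (downward, adjusted p = 0.0943, and adjusted p = 0.769 with an estimated correlation), but without SPIB replicate 2 it did (adjusted p = 0.00315), with 8 members lower and 2 higher. With KRAS replicate 1 left out the list held 1 higher and 1 lower member, Dclk1 and Fyb, without KRAS replicate 2 it held 1 and 2, and without SPIB replicate 1 it held 2 and 2.

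Of 24 ductal epithelial markers 10 rose and 0 fell, or 12 and 0 when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.000163) and did not with an estimated one (adjusted p = 0.769 with an estimated correlation). Dcdc2a, a ciliary protein gene, rose by a log2 of 0.82 ± 0.13 from 84.0 to 149 CPM. The chloride channel Cftr rose by 0.56 ± 0.13, the bicarbonate transporter Slc4a4 by 0.56 ± 0.14 and the RNA-binding protein gene Bicc1 by 0.53 ± 0.15. Krt8, Krt18, Sox9 and Clu were also among the members that rose. Dcdc2a alone was called without KRAS replicate 1, and without KRAS replicate 2 the list held 2 higher members. The acinar list did not pass camera (adjusted p = 0.0742, and adjusted p = 0.769 with an estimated correlation). Of 13 acinar markers tested, 5 fell, 2 rose and 6 were not called, the same counts as when adjusted over the list alone, and the amylase genes Amy1 (log2 -3.16 ± 0.46) and Amy2a5 (log2 -2.07 ± 0.54) and the elastase gene Cela2a (log2 -2.19 ± 0.73) fell from means of 2.37, 1.18 and 0.521 CPM, while the lipase-related gene Pnliprp2 rose (log2 0.52 ± 0.17). The amylase genes are near-identical copies whose reads may have been divided between them, and 17 of 30 acinar markers were too low to test. Amy1 was the 1 acinar marker called without KRAS replicate 1, without KRAS replicate 2 the list held 1 higher and 1 lower member, and without SPIB replicate 1 it held 1 higher and 2 lower members.

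Among 33 cell cycle genes, 15 rose and 2 fell, or 18 and 2 when adjusted over the list alone. The replication helicase subunits rose, Mcm4 by a log2 of 0.81 ± 0.13 (61.2 to 107 CPM), Mcm3 by 0.82 ± 0.14 and Mcm2 by 0.78 ± 0.14, and the mitotic genes Top2a, Plk1 and Ccna2 rose as well. Cenpa, the centromeric histone, went against the list with a log2 of -0.86 ± 0.14 (60.9 to 33.4 CPM), as did Ccne2 (log2 -0.55 ± 0.15). The list passed camera (adjusted p = 0.000301) and did not with an estimated correlation (adjusted p = 0.769 with an estimated correlation). It held 5 higher and 1 lower member without KRAS replicate 1, and without KRAS replicate 2 it held 4 and 2. Mcm2, Mcm3, Mcm4 and Cenpa were called without each of the 4 libraries.

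In the antigen presentation list 8 of 17 members rose and 0 fell, the same counts as when adjusted over the list alone. Erap1, an aminopeptidase that trims peptides for MHC class I, went from 64.7 to 127 CPM (log2 0.98 ± 0.13, adjusted p = 2.63e-05), and Cd74, the MHC class II invariant chain, from 18.0 to 33.3 CPM (log2 0.89 ± 0.14, adjusted p = 0.00023). H2-K1 (log2 0.66 ± 0.13), which shares sequence with H2-D1, and the tapasin gene Tapbp (log2 0.62 ± 0.13) also rose. Camera gave an adjusted p of 0.00853 (adjusted p = 0.769 with an estimated correlation), and the list held 2 higher members without KRAS replicate 1 and 5 without KRAS replicate 2. Interferon response genes did not pass camera (adjusted p = 0.0742), with 8 of 32 members higher and 3 lower by both adjustments. Stat1 (log2 0.73 ± 0.12), Ifit2 (log2 0.76 ± 0.17), Ifih1 (log2 0.57 ± 0.13) and Irgm1 (log2 0.55 ± 0.12) rose, while Stat2, Mx1 and Mx2 fell. Stat1 was the 1 member called without KRAS replicate 1, and without KRAS replicate 2 the list held 3 higher and 1 lower.

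Sterol and fatty acid synthesis genes had 7 of 24 members higher and 0 lower, also when adjusted over the list alone. The fatty acid enzymes Acaca (log2 0.69 ± 0.17) and Acly (log2 0.53 ± 0.14) and the sterol enzymes Dhcr24 (log2 0.52 ± 0.14) and Sqle (log2 0.45 ± 0.13) were among them. Camera gave an adjusted p of 0.0114 (adjusted p = 0.769 with an estimated correlation), and edgeR called 0 members without KRAS replicate 1 and 0 without KRAS replicate 2, where 3 and 7 members were higher at an unadjusted p under 0.05. The unfolded protein and amino acid stress list had 5 higher and 1 lower of 22 (4 and 1 adjusted over the list alone) and did not pass camera (adjusted p = 0.119). Ddit3, the stress transcription factor CHOP, fell by 1.27 ± 0.26 on the log2 scale, while the asparagine synthetase gene Asns (log2 0.52 ± 0.13), the cystine transporter Slc7a11 (log2 0.56 ± 0.14) and the chaperone Hsp90b1 (log2 0.55 ± 0.16) rose. In that list edgeR called 0 members without KRAS replicate 1, with 2 higher and 2 lower at an unadjusted p under 0.05, and without KRAS replicate 2 it called Ddit3 alone. The p53 response list had 5 higher and 0 lower of 20, but 1 and 0 when adjusted over the list alone (camera adjusted p = 0.0908), with Zmat3 (log2 0.49 ± 0.13), Cdkn2a (log2 0.52 ± 0.18), Pmaip1 (log2 0.35 ± 0.13) and Cdkn1a (log2 0.36 ± 0.13) named. Leaving out KRAS replicate 1 or KRAS replicate 2 left 0 by edgeR, with 1 and 4 members higher at an unadjusted p under 0.05. Medians of the ductal, cell cycle, antigen presentation, sterol and p53 lists stayed positive without any 1 library. With all 4 libraries they were 0.43, 0.34, 0.26, 0.28 and 0.14. Without KRAS replicate 1 they were 0.39, 0.40, 0.20, 0.23 and 0.14, and without KRAS replicate 2 0.48, 0.25, 0.42, 0.31 and 0.18. Without SPIB replicate 1 they were 0.44, 0.26, 0.29, 0.27 and 0.11, and without SPIB replicate 2 0.34, 0.42, 0.32, 0.25 and 0.26. The counts of calls moved with the scaling. Upper-quartile scaling gave 7 higher and 0 lower ductal markers, 12 and 2 cell cycle, 7 and 0 antigen presentation, 6 and 0 sterol and 1 and 0 p53 genes. On log2(TPM + 1) values the counts were 16 and 0, 19 and 1, 10 and 0, 12 and 0, and 7 and 0. After trends with GC content and length were removed they were 20 and 1, 25 and 1, 11 and 0, 12 and 0, and 10 and 1.

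Of 13 mitochondrially encoded genes 10 fell and 0 rose (11 and 0 adjusted over the list alone). mt-Co1 (log2 -1.38 ± 0.29), mt-Nd5 (log2 -1.25 ± 0.26), mt-Cytb (log2 -1.15 ± 0.26) and mt-Atp6 (log2 -1.11 ± 0.26), subunits of the respiratory chain, had the smallest p. These genes took 10.4% and 6.76% of the counts in KRAS replicates 1 and 2 and 2.93% and 4.46% in SPIB replicates 1 and 2. Of 29 ribosomal protein genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), with Rpl10 at log2 -1.10 ± 0.15, Rpl32 at -0.79 ± 0.17, Rps19 at -0.78 ± 0.16 and Rpl27 at -0.60 ± 0.13. Camera gave adjusted p of 0.00057 and 0.00196 for these lists (adjusted p = 0.769 with an estimated correlation for both). Without KRAS replicate 1 the lists held 1 and 3 lower members, without KRAS replicate 2 they held 11 and 1, without SPIB replicate 1 they held 9 and 7, and without SPIB replicate 2 they held 12 and 22. On log2(TPM + 1) values 2 ribosomal protein genes were higher and 4 lower, where the median of all genes shifted by 0.19. After trends with GC content and length were removed, 1 mitochondrially encoded gene was higher and 4 lower, and the list median went from -1.15 to -0.27. That fit, added after the data were seen, had 3 ribosomal protein genes higher and 7 lower. Their median went from -0.38 to -0.08. Both families have near-identical nuclear pseudogene copies to which reads can be divided.

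**Figure D2:**
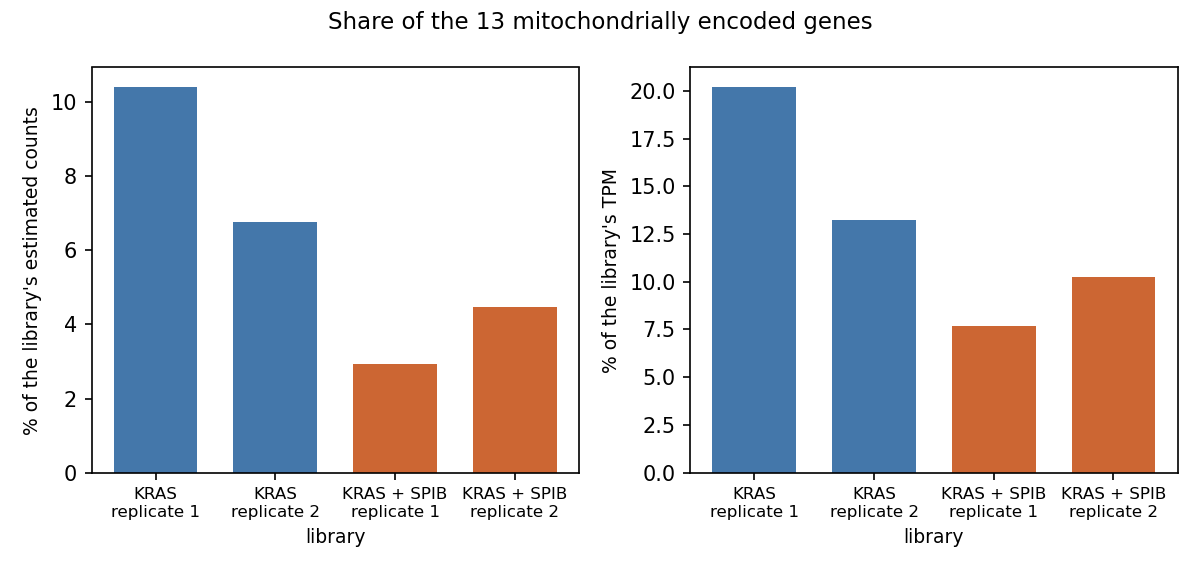
Share of the 13 mitochondrially encoded genes in each library (bars from 0, one per library) as a percentage of its estimated counts on the left and of its TPM on the right. Both KRAS libraries lay above both SPIB libraries, with 10.4% and 6.76% against 2.93% and 4.46% of counts.

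The mitochondrial share moved with every gene group above, since both KRAS libraries had a higher share than both SPIB libraries. It also differed within groups, and on the first principal component, which held 70.3% of the variance of log2 CPM, the libraries stood at -47.5 and -32.6 for KRAS replicates 1 and 2 and at 46.5 and 33.7 for SPIB replicates 1 and 2. With that share as a covariate, added after the data were seen, 10 genes were called higher and 37 lower, with 690 genes at an unadjusted p under 0.05. Spib, Fyb, Iapp, Rpl10, Rgs11, Kifc2, Lime1 and Spaca6 were the named genes that kept their call there. The ductal, cell cycle, antigen presentation, sterol and mitochondrial lists each held 0 members called by edgeR in that fit, with 1, 3, 2, 0 and 1 members at an unadjusted p under 0.05. The list medians went from 0.43 to 0.30 (ductal), 0.34 to 0.43 (cell cycle), 0.26 to 0.30 (antigen presentation), 0.28 to 0.15 (sterol), -0.38 to -0.47 (ribosomal protein) and, for the genes that make up the share, -1.15 to -0.06. Among the other 18 lists the largest moves were -0.92 to -3.54 (endocrine), 0.51 to -0.50 (fibroblast and stellate), 0.64 to 0.16 (mesenchymal), -0.27 to 0.04 (tuft), -0.79 to -1.09 (acinar) and -0.46 to -0.16 (endothelial). The median SE of the genes called higher from all 4 libraries without the covariate went from 0.13 to 0.34.

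In the mesenchymal transition list 7 of 17 genes rose and 2 fell by both adjustments (camera adjusted p = 0.276). Fibronectin, Fn1, rose from 732 to 1270 CPM (log2 0.79 ± 0.18), Sparc by a log2 of 0.64 ± 0.13 and the metalloproteinase Mmp14 by 0.62 ± 0.14, while S100a4 (log2 -1.15 ± 0.29) and Tgfbi (log2 -2.35 ± 0.78) fell. The RAS-ERK output list had 5 higher and 1 lower of 24 by both adjustments (camera adjusted p = 0.306), with the Ets factor Etv5 (log2 0.49 ± 0.13), Epha4 (log2 0.51 ± 0.13) and the ERK inhibitor Spred1 (log2 0.43 ± 0.13) higher and Spred3 lower (log2 -1.35 ± 0.18). Of NF-kB and chemokine genes 5 rose and 5 fell of 27 (5 and 7 adjusted over the list alone, camera adjusted p = 0.960). Nfkbiz (log2 -0.90 ± 0.14), Cxcl2 (log2 -0.65 ± 0.15) and the cytokine Csf2 (log2 -0.69 ± 0.16) fell and Sod2 (log2 0.57 ± 0.13) rose. Among type 2 alarmins and eicosanoid enzymes 2 of 18 rose and 2 fell by both adjustments (camera adjusted p = 0.747), the alarmin Il33 (log2 0.68 ± 0.14) and leukotriene A4 hydrolase, Lta4h (log2 0.47 ± 0.12), being higher and Il17rb and thromboxane synthase, Tbxas1 (log2 -1.28 ± 0.35), lower. Without KRAS replicate 1 the numbers higher and lower were 0 and 0 in the mesenchymal list, 0 and 1 in the RAS-ERK list, 0 and 1 in the NF-kB list and 0 and 0 in the type 2 list, and without KRAS replicate 2 they were 4 and 0, 0 and 1, 1 and 3, and 1 and 2. Where edgeR called none, 7 mesenchymal genes were higher and 2 lower at an unadjusted p under 0.05, and 2 type 2 genes were higher and 2 lower.

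Gastric and mucous metaplasia genes split into 5 higher and 5 lower of 21 by both adjustments (camera adjusted p = 0.612). The gastric mucin Muc5ac (log2 0.87 ± 0.16) and the gastric claudin Cldn18 (log2 0.69 ± 0.14) rose, and the transcription factor Onecut2 (log2 -1.01 ± 0.18, from 754 to 374 CPM) and Anxa10 (log2 -0.60 ± 0.12) fell. Of M cell genes 2 rose and 4 fell of 13 (2 and 5 adjusted over the list alone, camera adjusted p = 0.747), with Anxa5 (log2 0.69 ± 0.15) and Marcksl1 (log2 0.57 ± 0.13) higher and Serpinb6a (log2 -0.59 ± 0.16) and Aif1 (log2 -0.74 ± 0.24) lower. Of Ets factor targets of B and dendritic cells 2 rose and 4 fell of 15 (2 and 5 adjusted over the list alone, camera adjusted p = 0.480). The actin bundler Lcp1 (log2 0.77 ± 0.15) and the kinase Lyn (log2 0.46 ± 0.13) rose, and Cd40 (log2 -0.95 ± 0.25) and Cd22 (log2 -2.50 ± 0.69) fell, Cd22 from 0.563 CPM. Without SPIB replicate 1 the list medians went from -0.38 to 0.0039 (gastric), -0.09 to -0.01 (M cell) and -0.34 to -0.49 (Ets targets). Without SPIB replicate 2 the medians were -0.57, -0.21 and -0.37. With KRAS replicate 1 left out these 3 lists held 1, 0 and 1 higher and 0, 0 and 1 lower members, and without KRAS replicate 2 they held 2, 1 and 1 higher and 2, 0 and 0 lower members. In the M cell list without KRAS replicate 1, where edgeR called none, 2 members were higher and 3 lower at an unadjusted p under 0.05.

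Endocrine markers had 2 higher and 2 lower of 13 by both adjustments (camera adjusted p = 0.392). Cpe and the beta cell factor Nkx6-1 (log2 0.69 ± 0.25) rose, and the islet hormone gene Iapp (log2 -1.80 ± 0.47) and the convertase Pcsk2 (log2 -3.52 ± 0.73, from 0.670 CPM) fell. The endocrine list held 1 higher and 3 lower members without KRAS replicate 1, where it passed camera (adjusted p = 0.0132), while with all 4 libraries it did not (adjusted p = 0.769 with an estimated correlation). It held 1 and 1 without KRAS replicate 2, where its median went from -0.92 to 0.44. It held 1 and 2 without SPIB replicate 1 and 2 and 2 without SPIB replicate 2. Nkx6-1 lost its call without either KRAS library and without SPIB replicate 1. Hypoxia and glycolysis genes had 2 higher and 2 lower of 21 (0 and 1 adjusted over the list alone, camera adjusted p = 0.480), with Slc2a1 (log2 0.38 ± 0.13) and Eno1 (log2 0.46 ± 0.16) higher and Higd1a (log2 -0.58 ± 0.14) and Pdk1 (log2 -0.54 ± 0.16) lower. All 4 lost their call without either KRAS library. In that list edgeR called 0 members without KRAS replicate 1 (0 higher and 3 lower at an unadjusted p under 0.05) and 0 higher and 1 lower without KRAS replicate 2. Leaving out SPIB replicate 1 gave 1 higher and 7 lower members. Leaving out SPIB replicate 2 gave 1 and 10 and a list that passed camera (adjusted p = 0.0228), while with an estimated correlation from all 4 libraries it did not (adjusted p = 0.889 with an estimated correlation). Of 16 Wnt and Notch targets 1 was lower and 0 higher by both adjustments (camera adjusted p = 0.971). That gene was the Wnt inhibitor Nkd1 (log2 -2.50 ± 0.63, from 0.887 CPM), which lost its call without either KRAS library and without SPIB replicate 1, and Nrarp (log2 0.39), Rnf43 (log2 -0.35) and Tcf7 (log2 0.38) did not pass.

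Markers of cells outside the epithelium were mostly low. Exceptions included Cd14, at 403 CPM in KRAS and 509 CPM in SPIB organoids, and Rgs5, at 31.5 and 44.3 CPM. Of 10 fibroblast and stellate cell markers tested, Acta2 (log2 0.64 ± 0.23, from 4.22 to 6.57 CPM) and Rgs5 (log2 0.49 ± 0.13) were higher and Thy1 (log2 -1.56 ± 0.22) was lower by both adjustments (camera adjusted p = 0.279), and Postn (log2 1.17 ± 0.56) did not pass. The fibroblast and stellate list had a median of 0.51 and did not pass camera with an estimated correlation either (adjusted p = 0.769). Its median was 0.40 without KRAS replicate 1 and 0.77 without KRAS replicate 2. Without SPIB replicate 1 it was 0.09, and without SPIB replicate 2 it was 0.84. Acta2 and Rgs5 lost their calls without either KRAS library. Of 5 endothelial markers tested Pecam1 fell from 24.8 to 11.8 CPM (log2 -1.08 ± 0.23), the 1 member called by either adjustment, while Vwf (log2 -1.06), Esam (log2 -0.46) and Flt1 (log2 -0.21) did not pass (camera adjusted p = 0.0943). Of 8 macrophage and T cell markers tested Cd3d (log2 -2.09 ± 0.52) and Lyz2 (log2 -1.35 ± 0.42) fell by both adjustments, from 1.08 and 1.73 CPM, and Cd68 (log2 -0.66) and Cd14 (log2 0.34) did not pass (camera adjusted p = 0.102). Thy1 was the 1 marker of these 3 lists called without KRAS replicate 1. The median, the mean and the camera direction of a list differed in sign for the NF-kB, type 2 and Wnt and Notch lists, whose medians were 0.0071, 0.0095 and 0.014 and whose means were -0.12, -0.12 and -0.20.

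**Figure D3:**
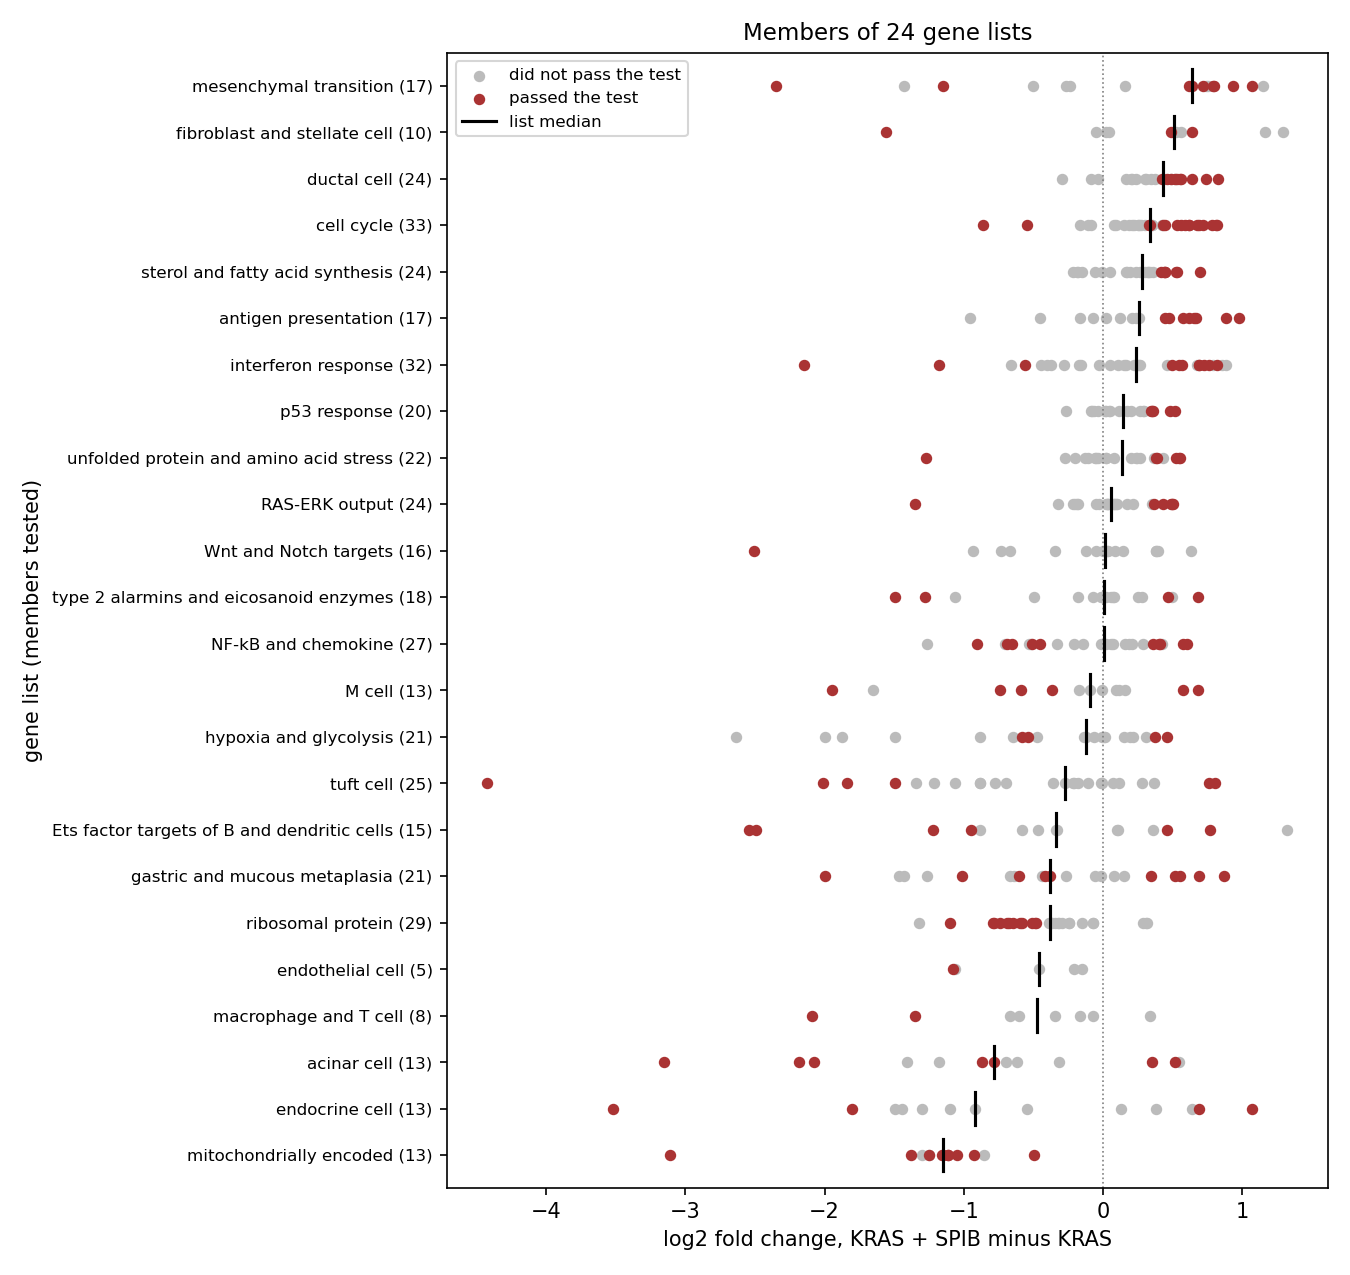
Log2 fold change (horizontal axis, SPIB minus KRAS organoids) of the tested members of 24 gene lists (vertical axis, with the number tested in brackets), red where the member passed edgeR's test, grey where it did not, and a black tick at the list median. The ductal list holds 10 higher and 0 lower calls and the mitochondrially encoded list 0 higher and 10 lower.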

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

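The fits with the mitochondrial share as a covariate, without the mitochondrially encoded genes and with trends of GC content and length removed were chosen after the data were seen. Where a value changed, the cause was not tested unless a reason is given. The direction of Spib held under every alternative tried, and its call held except with limma on log2(TPM + 1) without a filter (log2 5.56, adjusted p = 0.103), which called 0 genes higher and 0 lower, with 5698 at an unadjusted p under 0.05. The higher calls, 2132 with all choices as planned, were 1370 with upper-quartile scaling, 55 at 2-fold, 10 with the covariate and 4400 with GC content and length trends removed, and ranged from 111 to 2997 with a library left out. The lower calls, 2570 as planned, were 1055 at 2-fold, 1233 on log2(TPM + 1), 1191 on log2(TPM + 0.1) and 37 with the covariate, and ranged from 561 to 3160 with a library left out. Leaving out a library leaves 1 fewer degree of freedom, and the lone library is assumed to vary like the pair in the other group. Against the planned scaling, the median of all genes moved by 0.19 and 0.20 log2 units on the 2 TPM scales and by 0.12 with GC content and length trends removed.

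The paired fit with the replicate number as a block called 2505 genes higher and 2700 lower. The deviations of same-numbered libraries had a correlation of -0.0048, which gave no sign that the numbers pair the samples. In that replicate block fit Spib had a log2 fold change of 6.13 and the tuft cell list an adjusted p of 0.106. Nid1 was not called (adjusted p = 0.0564), Kras (0.0402) and Cd14 (0.0479) were, and so were the acinar (0.0279) and interferon (0.0393) lists (adjusted p = 0.769 with an estimated correlation for both without the block), while no other call of a named gene or list changed.

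The tuft cell list ranged from an adjusted p of 0.00315 to 0.634 with a library left out and passed only without SPIB replicate 2. Of 388 list results under alternatives, 323 kept their side of the threshold and direction, 19 no longer passed, 24 newly passed and 22 changed direction, none of these 22 past the threshold. Most of the 323 belong to lists that did not pass as planned. The 6 lists that did pass all failed with fry (adjusted p = 0.191 to 0.338) and with an estimated correlation (adjusted p = 0.769). With an estimated correlation none of the 24 lists passed, on 2 residual degrees of freedom. The endothelial list, whose estimated correlation was -0.030, went there from an unadjusted camera p of 0.0432 to 0.175. Of 2207 results for named genes, 1788 kept both, 395 lost the call, 21 gained it and 3 changed sign. Those were Kras (log2 0.050) and Pnliprp2 (log2 -0.094) with the covariate and Pou2f3 (log2 0.15) without SPIB replicate 1, against -2.84 without SPIB replicate 2, where it was called lower (adjusted p = 0.0396). With each library left out in turn, adjusted p ranged from 0.401 to 0.965 for M cell, 0.0977 to 0.867 for gastric, 0.0132 (without KRAS replicate 1) to 0.826 for endocrine and 0.856 to 0.953 for NF-kB genes. The adjusted p of lists that changed direction follow. Without a filter they were 0.535 for M cell, 0.876 for gastric and 0.966 for Wnt and Notch genes. With a minimum of 1 CPM they were 0.589 for endocrine, 0.910 for NF-kB and 0.910 for Wnt and Notch genes. Without KRAS replicate 1 it was 0.824 for Wnt and Notch genes. Without KRAS replicate 2 they were 0.965 for M cell, 0.867 for gastric and 0.826 for endocrine genes. Without SPIB replicate 1 they were 0.871 for M cell and 0.480 for gastric genes, and without SPIB replicate 2 they were 0.953 for both NF-kB and Wnt and Notch genes. On log2(TPM + 1) they were 0.809 for M cell and 0.900 for NF-kB and fibroblast genes, with fry 0.687 for NF-kB genes, and without the member with the smallest p 0.770 for Wnt and Notch genes. With the covariate they were 0.962 for Wnt and Notch, 0.942 for hypoxia and 0.343 for fibroblast genes. Depth weighed most on genes with a mean under 50 counts, where the median chi-square within replicate pairs was 1.08 (KRAS) and 1.37 (SPIB), nearer the 0.455 of counting error alone than the 5.63 and 11.5 at 500 counts or more. The SPIB counts of Pou2f3 differed by more than counting error (chi-square 11.7).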

Other observations

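The tests of a library property that varies between replicates and of tuft cell number, and the fits with the mitochondrial share as a covariate and with trends of GC content and length removed, were chosen after the result was seen, as was the use of unadjusted p for effective length.

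Effective transcript length, the estimated count divided by TPM, shows which transcripts of a gene the reads were assigned to. With limma on 11887 genes with enough counts, 0 genes passed the adjusted threshold, while 3659 had an unadjusted p under 0.05. Those were 31.7% of the higher, 34.1% of the lower and 29.8% of the uncalled genes. Such shares lie well above what a threshold of 0.05 gives for unchanged genes, and the smallest adjusted p was 0.107. The 0 calls therefore do not show that transcript use was unchanged.

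The 2570 genes called lower in SPIB organoids had a median log2 fold change of -0.84 and a lower median expression, at 3.96 log2 CPM, than the 2132 higher ones, at 6.14. The tables argue against GC content or transcript length as the whole cause, since with both trends removed 76.3% of the lower calls that have these values remained called, with a median log2 that went from -0.80 to -0.62. They do not exclude it for the mitochondrially encoded genes, where the lower calls went from 10 to 4, or for ribosomal protein genes, where they went from 12 to 7. Unspliced or nuclear RNA, or another library property tied to the mitochondrial share, could contribute and stays open. With expression in the model, protein-coding lower calls more often had an annotated retained intron than higher calls (odds ratio 1.93, 95% confidence interval 1.67 to 2.24). With length and GC content added to that model the odds ratio was 2.45 (2.09 to 2.87). Both intervals take genes as independent. Without any of these terms the shares were closer, at 61.9% of lower, 58.3% of higher and 54.8% of uncalled protein-coding genes. Of the 2560 nuclear lower calls of any gene type, 75.1% within the KRAS pair and 66.0% within the SPIB pair were higher in the library with the larger mitochondrial share. Within the pairs this held for 49.0% and 50.6% of uncalled genes and 25.2% and 23.7% of the 2132 higher calls. Each share comes from a single pair of libraries over genes that are not independent, and the higher calls follow the mitochondrial share as well, in the other direction. With that share as a covariate the median of the lower calls went from -0.84 (median SE 0.17) to -0.56 (median SE 0.37) with 98.6% in the same direction. The share accounts for 75.4% of the variance of the group label over the 4 libraries. That value measures how far share and group overlap, not how much of the expression difference the share explains. The fit leaves 1 residual degree of freedom, and how far the smaller fold, the larger SE and the lost degree of freedom each ended calls was not separated. A change in the transcripts used cannot be told apart from a change in gene output, since no effective length passed its test and lower calls had an unadjusted p under 0.05 1.14 times as often as uncalled genes (95% confidence interval 1.07 to 1.23, with genes taken as independent), and a response to SPIB, which may itself include the mitochondrial share, stays open as untested.

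Dclk1 rose in SPIB organoids (log2 0.76 ± 0.13), and of the other 24 tested tuft cell markers Kctd12 rose (log2 0.80 ± 0.24) and 4 fell. The tables argue against more tuft cells as the cause, since the other 24 tested markers had a median log2 fold change of -0.31 with an interquartile half-range of 0.54. That median was -0.12 (half-range 0.61) without SPIB replicate 1 and -0.76 (half-range 1.16) without SPIB replicate 2. From all 4 libraries, 1 of these markers reached the change of Dclk1 less its SE. Their median plus half-range also stayed below that bound without each library, with upper-quartile scaling, with the GC content and length trends removed and, for 9 markers, on log2(TPM + 1) values (median 0.03 against 0.91 ± 0.21 for Dclk1). It did not with the covariate, where Dclk1 was not called (log2 0.71 ± 0.34) and the others had a median of -0.02 with a half-range of 0.60. The tables also argue against more fibroblasts rich in Col1a1, Col1a2, Col3a1, Dcn and Lum as the source. These 5 genes together stood at 6.50 ± 3.75 CPM (SD, n = 2) in SPIB organoids and 5.34 ± 1.11 in KRAS organoids. That was far below Dclk1, which went from 27.2 to 46.2 CPM. Cells low in these 5 genes are not covered by that sum. The fibroblast and stellate list as a whole had a median log2 of 0.51. Its median was 0.09 without SPIB replicate 1 and 0.84 without SPIB replicate 2. Without KRAS replicates 1 and 2 in turn it was 0.40 and 0.77. In that list Acta2 and Rgs5 (31.5 to 44.3 CPM) were higher and Thy1 was lower. A change in stellate or similar cells is therefore not excluded, also as a source of the rise in Dclk1. A rise of Dclk1 within the epithelial cells in response to SPIB may be the source and stays a hypothesis, which these bulk libraries do not test.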
